A study of Mus musculus with 6 samples.

How the data were processed

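RNA sequencing libraries were made from postmitotic neurons of mouse cortex at stage E14.5, with 3 libraries from control embryos carrying both copies of Rp58 (Zbtb18) and 3 from mutant embryos carrying none. Per the labels, a stranded total RNA kit and 1 sequencer model were used for the whole series. The submitters' processing notes name FastQC, kallisto and the mm9 build, and give no versions. Each deposited table listed the same 97251 transcripts with 4 values each. Per the deposited files' headers, these were the length, the effective length, the estimated count and the TPM value, which is scaled by effective length and total. The estimated count is a number of reads assigned to a transcript by kallisto, need not be whole, and was deposited without further normalization by the authors. The TPM values were deposited as the authors' own scaling of those estimated counts by effective length and by the total. The length and effective length, in bases, were deposited by the authors for each transcript and library.

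The effective lengths showed 2 technical sets of 3 libraries. The fixed-length set held control 1, mutant 1 and mutant 2, and the estimated-length set held control 2, control 3 and mutant 3. The labels name no such sets, and the sets were defined from the deposited lengths, without regard to the expression of any gene. What made them differ is not given in the sources used here.

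Transcript identifiers were joined to genes of the GENCODE vM21 annotation, which was used for gene names only. Of the 97251 transcripts, 84637 (87.0%) matched, and 12614 did not. The latter took between 6.85% and 8.58% of the counts of a library and stayed out of the gene tests. Since the notes name mm9 and the annotation is of a later build, no coordinates are given. Estimated counts were summed to 34289 genes and rounded to whole numbers. Counts of near-identical genes, such as those of the hemoglobins and histones, are uncertain, because kallisto divides shared reads between them. Total counts and their spread between libraries are given with the results.

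Genotypes were compared with the quasi-likelihood test of edgeR (version 4.0.16, in R 4.3.3) on all 6 libraries, with TMM normalization, filterByExpr at its default settings, a prior count of 2 and no covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and 16985 genes were tested. The standard error of a log2 fold change was its size divided by the square root of F. The same fit with a term for technical set, one of the alternatives chosen before the data were examined, is printed beside it, because the sets raised the common biological coefficient of variation from 0.186 with the term to 0.701 without it. Effects within each set came from a fit with separate genotype effects and a spread pooled over both sets, since each set holds 1 genotype with a single library. That fit, the leave-one-out and scaling fits with the set term, and the set term for single transcripts were chosen after the data were seen. Levels are given as CPM, counts scaled to the normalized library size, with SD over 3 libraries. Where no control library had a count, the fold is a lower bound against 3 counts over the group, and such floors cover counting error only. Single transcripts were tested in the same way.

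Before the data were examined, 37 gene lists with 655 members were fixed from textbook knowledge. They covered the Id family, neurogenic genes reported earlier as repressed by RP58, radial glia, cell cycle, intermediate progenitors, pan-neuronal genes, glutamatergic and synaptic genes, deep-layer and upper-layer neurons, subplate, Cajal-Retzius cells, interneurons, striatal neurons, hippocampus and cortical hem, astrocytes, the oligodendrocyte lineage, endothelial, mural and meningeal cells, extracellular matrix, microglia, erythroid cells, choroid plexus and ependyma, muscle, 3 glioblastoma subtypes, the BMP and TGF-beta, Notch and Wnt pathways, neuronal migration, axon guidance, p53 response, immediate early genes, hypoxia and glycolysis, mitochondrially encoded genes and sex-linked genes. Each list was tested with camera of limma (version 3.58.1) at a preset correlation of 0.01, adjusted over the 37 lists. It was tested again with fry and with an estimated correlation, where camera takes its degrees of freedom from the 6 libraries and passes fewer lists. Members called were counted over all genes and adjusted over the list alone.

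Also before the data were examined, a rule fixed which genes would be named. They were Zbtb18; Id1, Id2, Id3, Id4, Neurog2, Neurod1 and Rnd2; and the 6 largest rises and 6 largest falls among called protein-coding genes whose groups did not overlap and whose higher group had a mean of at least 2 CPM. From each list that passed or had at least 3 members called, the rule took up to 3 members with the smallest p, and from each other list the member with the highest mean CPM. Some genes that the rule takes are not reported here, though they remain in the tests and counts. Genes outside the rule are marked as chosen after their values were seen.

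Alternatives were other scalings (DESeq2 size factors, upper-quartile factors, library size only), other tests (DESeq2 1.42.0, limma-voom, limma on log2 TPM with a pseudocount of 1 or 0.1), other filters on low counts, an effective-length offset, protein-coding genes only, the set term, 1 surrogate variable (sva 3.50.0) and each library left out in turn. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

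The procedure was tested on simulated counts for the comparison of mutant with control, over 16985 genes with the means and library sizes of the real libraries and 200 genes changed. Without the set term it recovered 0%, 12%, 32% and 54% of genes changed 2-fold, 4-fold, 8-fold and 16-fold, and 0 of 49 calls were false. With the set term it recovered 50%, 76%, 90% and 90%, and 24 of 177 calls (13.6%) were false, which is above the nominal 5%. The list test called 5 of 5 simulated lists that moved and 1 of 20 that did not. Those lists held random genes simulated independently, and every member of a moved list was shifted equally. The real lists had estimated correlations of up to 0.85, so this does not show how often the list test errs on them.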

Results

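The series measured RNA by sequencing in postmitotic neurons from the cortices of mouse embryos at stage E14.5. It compared 2 genotypes with 3 libraries each. Control embryos carried both copies of Rp58, and mutant embryos carried none. Rp58 is the earlier name of Zbtb18, a zinc finger transcription factor that represses its target genes and that is required for cortical neurons to mature. The question stated by the design is how loss of this repressor changes the transcripts of these neurons. The labels do not say whether the 3 libraries of a genotype came from separate embryos or litters. The p-values therefore measure the spread between these libraries, which could be technical in part. Levels of Xist, given below, differed between libraries of each genotype, which argues against the same embryo as their common source. Libraries are numbered within each genotype in the order of deposition, and the numbers pair nothing.

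Total estimated counts were 34645505, 75892649 and 46457653 in control libraries 1, 2 and 3, and 56472475, 54078417 and 53044306 in mutant libraries 1, 2 and 3. Of the 97251 transcripts listed, between 49.1% and 71.5% had a count above 0 in a library. The libraries fell into 2 technical sets that crossed the genotypes unevenly. In control 1, mutant 1 and mutant 2, each long transcript was exactly 249 bases longer than its effective length, so 1 fixed fragment length had been given (the fixed-length set). In control 2, control 3 and mutant 3 that difference lay between 133.7 and 139.2 bases and varied between libraries (the estimated-length set). Transcripts without a poly(A) tail followed the same division. The small nuclear RNA Rn7sk had a mean of 4.54 CPM (counts scaled to the normalized library size) in the fixed-length set and 16700 in the estimated-length set, and the nuclear RNA Malat1 had 95.3 and 10100. Mitochondrially encoded transcripts took 3.58% to 5.15% of counts in the fixed-length set and 16.4% to 17.5% in the estimated-length set. On the 1000 most variable genes, the first principal component held 83.4% of the variance and separated the sets, while the second held 10.7% and separated the genotypes. Rank correlations across genes were between 0.963 and 0.992 for pairs of libraries within a set and between 0.884 and 0.918 for pairs across sets. No pair of libraries agreed within sampling noise, since chi-square per degree of freedom was 18.7 for the closest pair, controls 2 and 3. Because of this division, counts of genes and of list members are given without a term for technical set, as fixed in the design, and for most lists also with that term. Since the genotypes are spread unevenly over the sets, means and fold changes without the term also carry part of the difference between sets. For example, the log2 fold change of Tubb3 was 0.091 without the term. It was -0.188 within the fixed-length set and -0.288 within the estimated-length set. For single genes the value with the term is given mainly where it changes a call.

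**Figure D1:**
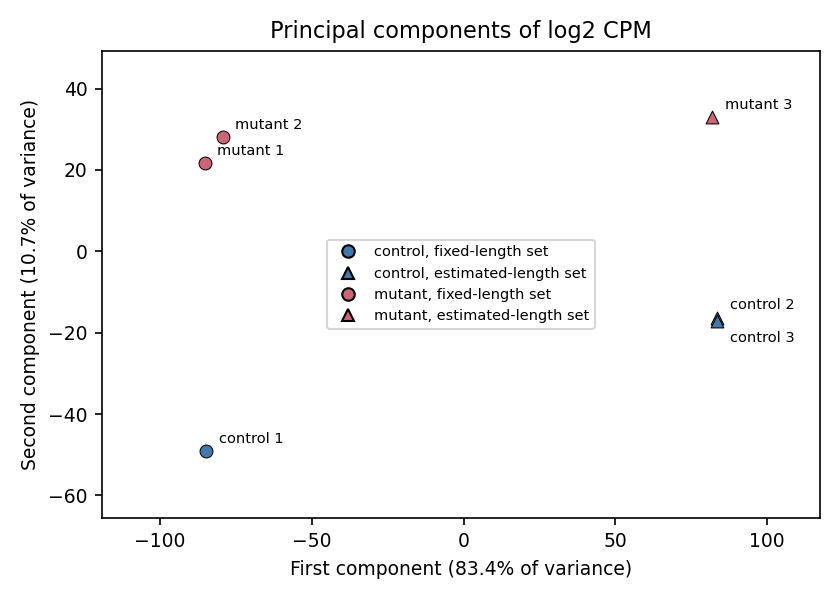
First against second principal component of log2 CPM over the 1000 most variable genes, 1 point per library, with circles for the fixed-length set and triangles for the estimated-length set. The first component (83.4% of variance) separates the sets and the second (10.7%) separates control (blue) from mutant (red) libraries.

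Zbtb18 itself was far lower in the mutant libraries. Its level was 1902, 1587 and 1697 CPM in controls 1, 2 and 3 and 46.7, 45.7 and 538 CPM in mutants 1, 2 and 3. In the fixed-length set, mutants 1 and 2 kept 2.5% and 2.4% of the control level, 40.8-fold and 41.7-fold below it. In the estimated-length set, mutant 3 kept 32.8% of the mean of its controls, 3.05-fold below it. All 3 mutants lay under all 3 controls, in the direction that the labels give. Why Zbtb18 remained in mutant 3 is open, and that library enters every mutant mean. Other values argue against a control library under a mutant label. Apart from Zbtb18, 36 genes with control means of at least 2 CPM in each set were called and fell at least 8-fold in the fixed-length set. These 36 genes kept a median of 8.8% of the control level in mutant 3, and 4 of them kept as large a share as Zbtb18 or a larger one. On the second principal component mutant 3 lay at 32.9, against -16.3 and -17.1 for controls 2 and 3. The log2 fold change of Zbtb18 was -3.04 ± 1.09 (SE) and was not called (adjusted p = 0.400). It was -3.48 ± 0.81 with adjusted p = 0.0337 with the set term, and -5.22 with adjusted p = 0.00583 without the set term when mutant 3 was left out. Both mutants of that last fit are of the fixed-length set, so it largely confounds genotype with set. When 1 library was left out of the fit with the set term, the adjusted p lay between 0.000199 and 0.119, and the call was lost without control 3, mutant 1 or mutant 2. The counts are shared between a spliced transcript (ENSMUST00000094276) and a transcript model with a single exon (ENSMUST00000077225). The single-exon model held 61.7% of the gene's counts in mutant 3 against at most 11.3% in controls 2 and 3, and 26.3% and 28.3% in mutants 1 and 2 against 1.9% in control 1. In level the sets went opposite ways. The single-exon model was at 331.8 CPM in mutant 3 against 179 and 187 CPM in controls 2 and 3, and at 12.3 and 12.9 CPM in mutants 1 and 2 against 36.5 CPM in control 1. The spliced transcript was lower in each mutant, at 206 CPM in mutant 3 against 1408 and 1510 CPM, and at 34.4 and 32.7 CPM against 1866 CPM.

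**Figure D2:**
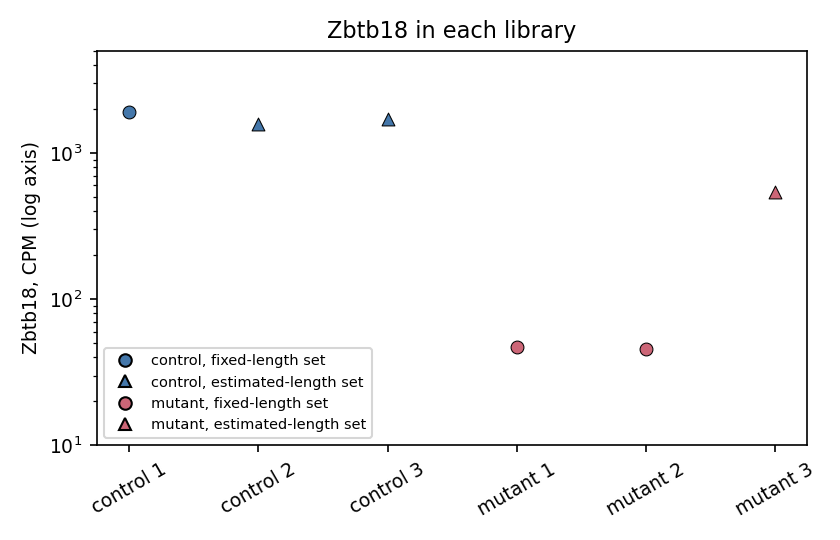
Zbtb18 in CPM on a log axis for each of the 6 libraries, 1 point per library, with circles for the fixed-length set and triangles for the estimated-length set. Controls lie between 1587 and 1902 CPM, mutants 1 and 2 lie at 46.7 and 45.7 CPM, and mutant 3 lies at 538 CPM.

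More genes rose than fell in the mutant neurons, and the largest rises reached transcripts that control neurons barely carried. Tac1, which encodes the precursor of substance P, and Kank2, an adaptor of focal adhesions, had no count in any control library. They reached 23.7 ± 13.2 and 6.64 ± 1.02 CPM in the mutants (SD, n = 3), at least 1111-fold and 311-fold above the floor of 3 counts over the control group. Lmcd1, a LIM domain protein that binds GATA factors, rose from 0.725 ± 0.064 to 358 ± 105 CPM. The neuropeptide gene Npy rose from 0.253 ± 0.213 to 124 ± 34.6 CPM, and Slc6a11, a GABA transporter, rose from 0.417 ± 0.081 to 109 ± 44.6 CPM. Gfra3, a receptor for the ligand artemin, had 4 counts in all controls together and 48.5 ± 14.2 CPM in the mutants.

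The largest falls included surface and signalling genes. Alcam, a cell adhesion molecule of growing axons, fell from 254 ± 67.9 to 7.07 ± 1.13 CPM (log2 fold change -5.17 ± 0.32, adjusted p = 0.00302). Prickle1, a planar cell polarity gene, fell from 41.3 ± 21.1 to 0.918 ± 0.346 CPM. Mc4r, the melanocortin receptor gene, fell from 39.4 ± 7.37 to 0.352 ± 0.132 CPM. The heparan sulfate sulfotransferase genes Hs3st3b1 and Hs3st5 fell from 13.4 ± 9.10 to 0.175 ± 0.035 CPM and from 7.10 ± 3.05 to 0.161 ± 0.017 CPM. The tight junction gene Cldn3 fell from 3.84 ± 1.06 to 0.0328 ± 0.0297 CPM. Among these 12 genes the adjusted p (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) ran from 0.00193 for Lmcd1 to 0.0344 for Cldn3, and from 5.85e-06 to 0.000963 with the set term.

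Of 16985 genes tested, 400 passed adjusted p 0.05, of which 270 rose and 130 fell. Adding the set term, 2537 passed, of which 1346 rose and 1191 fell, so the share that rose was 67.5% without and 53.1% with the term. All 400 genes were also called with the set term in the same direction, had the same sign within both sets, and had mutant libraries that did not overlap the controls. These properties come from the same 6 libraries as the calls and are not independent support. Groups that do not overlap necessarily have the same sign within both sets. Groups did not overlap in 15.4% of all tested genes. Chance would give 10% if the 6 libraries were interchangeable, which the technical sets contradict, so 10% is not an exact benchmark here. Changes of at least 8-fold were called for 121 genes that rose and 28 that fell, and for 196 and 55 with the set term. Within the fixed-length set 1606 genes were called and within the estimated-length set 1345, with the spread pooled over both sets because each holds a genotype with a single library. The effects differed between the sets for 26 genes in the test of that difference (1222 at an unadjusted p under 0.05). The count without the set term fell to 84 without control 2, 97 without control 3, 107 without mutant 1 and 96 without mutant 2, and was 277 without control 1 and 329 without mutant 3. Without control 1 both remaining controls are of the estimated-length set, and without mutant 3 both remaining mutants are of the fixed-length set. These fits largely confound genotype with set. Changes in calls and lists there cannot be told apart from an effect of the sets. The count with the set term was 1294, 1410 and 1429 without controls 1, 2 and 3 and 2106, 3034 and 1557 without mutants 1, 2 and 3. Of the 44 named genes called, 11 stayed called whichever library was left out: Alcam, Ebf1, Hes1, Lfng, Lmcd1, Lmo3, Mc4r, Met, Nr4a2, Slc6a11 and Timp3. In the fit with the set term 49 of 67 did so, and all 67 kept their direction in each such fit.

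**Figure D3:**
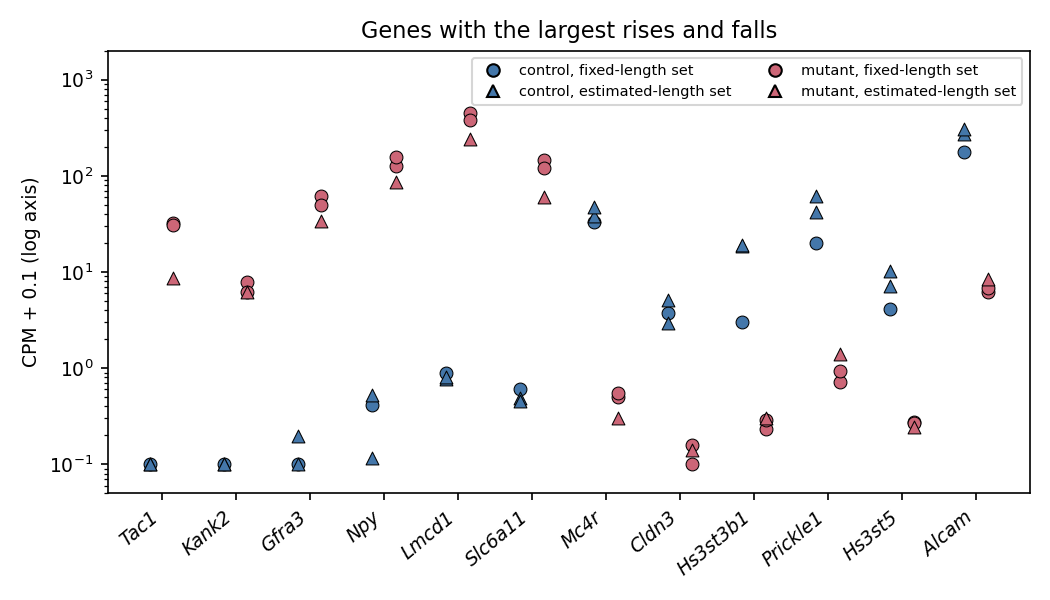
CPM plus 0.1 on a log axis for the 6 genes with the largest rises (left) and the 6 with the largest falls (right), 1 point per library, controls in blue, mutants in red, circles for the fixed-length set and triangles for the estimated-length set. For each gene the 3 mutant libraries lie on one side of the 3 controls, which the rule that chose the genes required. Alcam lay at 254 ± 67.9 CPM in controls and 7.07 ± 1.13 CPM in mutants (SD, n = 3).

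Neurog2 and Neurod1, proneural transcription factor genes that earlier work reported as repressed by RP58, rose in the mutants. Neurog2 rose 4.22-fold, from 21.7 ± 5.27 to 91.6 ± 8.82 CPM (log2 fold change 2.08 ± 0.23, adjusted p = 0.0117, and 0.000123 with the set term). Neurod1, which acts after Neurog2 in the same lineage, rose 6.93-fold, from 34.7 ± 19.7 to 240 ± 56.7 CPM (adjusted p = 0.0426, and 0.000384 with the set term). Rnd2, a GTPase of radial migration, had 489 ± 342 CPM in controls and 927 ± 481 CPM in mutants and was not called (adjusted p = 0.996). Its log2 fold change was 0.40 ± 0.10 with the set term (adjusted p = 0.0373), a call kept in 1 of 6 fits with a library left out, the one without mutant 2. Neurog1, a member of the same list chosen after its values were seen, had 0.209 ± 0.177 CPM in controls and 0.370 ± 0.318 CPM in mutants and was called in neither fit (adjusted p = 0.996 and 0.900). Of the 4 tested members of this list, 2 rose over all genes and also when adjusted over the list alone, and 3 rose with the set term. Camera gave the list adjusted p = 0.00189, and adjusted p = 0.369 with an estimated correlation.

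Among the Id genes, inhibitors of such factors, none was called without the set term over all genes, and 1 rose when adjusted over the list alone. Id4 had 9.68 ± 2.34 CPM in controls and 20.8 ± 3.33 CPM in mutants (log2 fold change 1.10 ± 0.26, adjusted p = 0.128). Id4 rose by 1.28 ± 0.13 with the set term (adjusted p = 0.00120), as did Id1 and Id3, which stayed under 1 CPM in both genotypes and whose calls were lost whichever library was left out. Id2, the most abundant member, had 293 ± 143 CPM in controls and 376 ± 126 CPM in mutants and was called in neither fit (adjusted p = 0.996 and 0.758). The list of 4 gave adjusted p = 0.00160, and adjusted p = 0.209 with an estimated correlation.

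Some members of the Notch and radial glia lists rose from low levels. Lfng, a glycosyltransferase that modifies Notch receptors, rose 80.5-fold, from 0.142 ± 0.021 to 11.7 ± 2.11 CPM (adjusted p = 0.00243). Hes1, a Notch target that holds progenitors undifferentiated, rose 32.4-fold, from 0.221 ± 0.041 to 7.20 ± 1.08 CPM (adjusted p = 0.00344). Pax6 rose from 6.72 ± 1.51 to 27.1 ± 4.70 CPM and Sox2 from 0.922 ± 0.050 to 5.40 ± 2.51 CPM (adjusted p = 0.0185 and 0.0433). Mfng, a relative of Lfng, had 12.8 ± 10.4 CPM in controls and 152 ± 70.5 CPM in mutants (adjusted p = 0.0841, and 6.03e-05 with the set term). Other transcripts of radial glia went the opposite way. The glutamate transporter gene Slc1a3 fell from 19.5 ± 5.63 to 6.002 ± 0.516 CPM (adjusted p = 0.0410). Ptprz1, Fabp7 and Vim, chosen after their values were seen, were called with the set term alone and fell by 2.05, 1.16 and 0.64 on the log2 scale (adjusted p = 0.000108, 0.000612 and 0.0140).

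In counts, 3 of 18 radial glia members rose and 1 fell, and 6 rose and 2 fell when adjusted over the list alone. The set term gave 8 that rose and 4 that fell. Camera gave this list adjusted p = 0.00214, and adjusted p = 0.263 with an estimated correlation, and the list did not pass within the fixed-length (0.106) or the estimated-length set (0.0784). In the Notch list 2 of 18 rose and none fell, 4 rose adjusted over the list alone, and 6 rose and 1 fell with the set term. Its adjusted p was 9.14e-05, and adjusted p = 0.209 with an estimated correlation. In the list of intermediate progenitors, Neurog2 rose and Cdh8, a cadherin gene also used by neurons, fell from 47.0 ± 8.27 to 19.9 ± 2.06 CPM (adjusted p = 0.0370). Over that list alone 7 of 13 members rose and 1 fell, and 7 rose and 1 fell with the set term. The list test gave adjusted p = 0.000319, and adjusted p = 0.361 with an estimated correlation. None of the 24 cell cycle genes was called over all genes or over the list alone without the set term, and 7 rose with it. Their median log2 fold change was 0.80 (0.56 with the set term), and most stayed at low levels, as with Mcm3 at 1.45 ± 0.89 CPM in controls and 4.18 ± 1.42 CPM in mutants and Cenpf at 2.46 ± 0.50 and 4.66 ± 0.78 CPM. The calls of both with the set term were lost in 5 of 6 fits with a library left out, all but the one without mutant 2 (adjusted p up to 0.183 and 0.308). Aurkb, at 0.277 ± 0.164 and 1.22 ± 0.68 CPM, was called in neither fit. The cell cycle list gave adjusted p = 1.07e-05, and adjusted p = 0.361 with an estimated correlation.

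Among genes that mark deep-layer cortical neurons, 4 of 13 fell. Lmo3, a LIM-only cofactor, fell from 69.4 ± 2.52 to 5.87 ± 1.88 CPM (log2 fold change -3.56 ± 0.30, adjusted p = 0.00482). Ldb2, a partner of LIM proteins, fell from 46.7 ± 12.4 to 8.004 ± 3.40 CPM and Sox5, a factor of corticofugal neurons, from 852 ± 269 to 210 ± 32.2 CPM (adjusted p = 0.0425 and 0.0410). None rose, 7 fell and 1 rose adjusted over the list alone, and 8 fell and 2 rose with the set term. Those 2, chosen after their values were seen, were Foxp2, from 14.4 ± 6.05 to 38.4 ± 13.7 CPM, and Nfia, from 591 ± 85.6 to 722.6 ± 65.1 CPM (adjusted p = 0.000561 and 0.0315 with the term). The list had adjusted p = 0.00193, and adjusted p = 0.361 with an estimated correlation, and it did not pass within the fixed-length set (0.0604). Among upper-layer genes 2 of 13 fell and none rose. Among them was Mef2c, a transcription factor gene chosen after its values were seen, from 11.8 ± 3.45 to 2.57 ± 0.61 CPM (adjusted p = 0.0386). Over the list alone 6 fell and 2 rose, 6 fell and 3 rose with the set term, and the most abundant member, Lhx2, rose with the set term alone (adjusted p = 0.00542, from 155 ± 57.1 to 296 ± 58.9 CPM, and 0.0639 without mutant 3). The upper-layer list did not pass (adjusted p = 0.340).

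Among subplate genes 1 of 7 tested members rose without and 4 with the set term. Nr4a2, an orphan nuclear receptor, rose 17.6-fold, from 3.29 ± 0.70 to 58.2 ± 8.94 CPM (adjusted p = 0.00302). Nxph4 had 33.1 ± 22.9 CPM in controls and 163 ± 85.5 CPM in mutants, and Nrgn 0.244 ± 0.124 and 1.31 ± 0.59 CPM. Both were called with the set term alone (adjusted p = 0.000451 and 0.0150), and the call of Nrgn was lost without control 1, control 2, control 3 or mutant 3 (adjusted p up to 0.133). Adjusted over the list alone 4 rose without the set term, and the list had adjusted p = 1.14e-06, and adjusted p = 0.241 with an estimated correlation. Among genes of Cajal-Retzius cells, the calcium-binding protein gene Calb2 rose from 4.003 ± 1.15 to 16.2 ± 3.40 CPM and Nhlh2 from 25 ± 5.56 to 72.1 ± 5.65 CPM (adjusted p = 0.0392 and 0.0255). Ebf3 had 7.75 ± 1.46 CPM in controls and 17.0 ± 1.54 CPM in mutants (adjusted p = 0.0744, and 0.00163 with the set term). The list had 2 of 11 members risen, 3 adjusted over the list alone and 3 with the set term, and adjusted p = 0.00206, and adjusted p = 0.361 with an estimated correlation. It was lost without control 1 (adjusted p = 0.116) and without mutant 3 (0.0912), fits that largely confound genotype with set. With the set term it passed (camera adjusted p = 0.00107, and 0.325 with an estimated correlation). Reln, the best-known product of these cells and chosen after its values were seen, had 481 ± 270 CPM in controls and 382 ± 245 CPM in mutants (adjusted p = 0.996).

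Tubb3, the neuronal tubulin, had 2579 ± 1032 CPM in controls and 2746 ± 1000 CPM in mutants. Its log2 fold change was 0.09 ± 0.46, and -0.24 ± 0.10 with the set term, and it was called in neither fit. In the pan-neuronal list 1 of 19 fell, and 1 rose and 1 fell adjusted over the list alone, while 3 rose and 5 fell with the set term. The member that fell in both fits was Syt4, a synaptotagmin gene chosen after its values were seen, from 86.7 ± 13.9 to 15.1 ± 3.40 CPM (adjusted p = 0.00805). The list test gave adjusted p = 0.962, with a median of 0.04 and a mean of -0.03. Of 20 glutamatergic and synaptic genes none was called over all genes and 1 rose adjusted over the list alone (list adjusted p = 0.783). In the fit with the set term 8 fell and 2 rose and the list passed downward (adjusted p = 0.0130, and adjusted p = 0.428 with an estimated correlation).

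Some genes of the axon guidance list rose and others fell. Nrp1, a semaphorin and VEGF receptor, fell from 192 ± 35.3 to 39.6 ± 11.9 CPM, while its relative Nrp2 rose from 47.8 ± 9.31 to 164 ± 44.4 CPM (adjusted p = 0.0202 and 0.0363). Sema6d fell from 192 ± 29.6 to 62.3 ± 15.5 CPM (adjusted p = 0.0421). In the axon guidance list 1 of 35 rose and 2 fell, 5 rose and 5 fell adjusted over the list alone, and 9 rose and 9 fell with the set term. The list test gave adjusted p = 0.943. In the migration list 1 of 24 rose and 1 fell, 2 rose and 2 fell adjusted over the list alone, 4 rose and 6 fell with the set term, and the list did not pass (adjusted p = 0.538). Plxna2 had 1039 ± 443 CPM in controls and 452 ± 206 CPM in mutants and was called with the set term alone (adjusted p = 0.00294).

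Members of the Wnt list also moved in both directions. Wnt7b fell 4.89-fold, from 461 ± 51.1 to 94.3 ± 21.6 CPM, and the receptor gene Fzd1 fell from 105 ± 5.53 to 23.7 ± 4.90 CPM (adjusted p = 0.0120 and 0.00805). Wnt7a rose from 5.31 ± 0.72 to 23.8 ± 7.48 CPM (adjusted p = 0.0254). In the Wnt list 1 of 25 rose and 2 fell, 3 rose and 2 fell adjusted over the list alone, 5 rose and 2 fell with the set term, and the list test, upward at adjusted p = 0.724, differed in sign from the median (-0.14). In the BMP and TGF-beta list 2 of 22 rose, 6 rose and 5 fell adjusted over the list alone, 6 rose and 6 fell with the set term, and the list did not pass (adjusted p = 0.783). Tgfbr1 had 179 ± 13.2 CPM in controls and 209 ± 18.7 CPM in mutants and was called in neither fit.

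Of 24 extracellular matrix genes 2 rose and 1 fell. Timp3, an inhibitor of matrix proteases, rose 10.4-fold, from 15.4 ± 0.58 to 159 ± 27.3 CPM, and the collagen gene Col5a1 rose from 4.29 ± 1.96 to 70.5 ± 26.9 CPM (adjusted p = 0.00302 and 0.0179). Fn1, fibronectin, fell from 29.4 ± 4.90 to 4.80 ± 1.38 CPM (adjusted p = 0.0102). Adjusted over the list alone 5 rose and 3 fell, 8 rose and 4 fell with the set term, and the list passed upward with adjusted p = 0.0273, and adjusted p = 0.568 with an estimated correlation. It was lost without control 1 (adjusted p = 0.337) and without mutant 3 (0.273). With the set term it passed (camera adjusted p = 0.00958, and 0.325 with an estimated correlation). Among genes of meningeal fibroblasts, Fbln1, a matrix glycoprotein, rose from 39.7 ± 6.56 to 432 ± 151 CPM (adjusted p = 0.00921). Islr had 0.906 ± 0.263 and 3.37 ± 0.18 CPM and Pdgfra 0.673 ± 0.084 and 1.77 ± 0.69 CPM, and both were called with the set term alone. The call of Pdgfra was lost without control 2, control 3 or mutant 3 (adjusted p up to 0.206). The collagen gene Col1a1, abundant in fibroblasts and chosen after its values were seen, had 0.360 ± 0.125 CPM in controls and 0.540 ± 0.120 CPM in mutants (adjusted p = 0.996). In this list 1 of 6 tested members rose, 2 adjusted over the list alone and 3 with the set term. Its adjusted p was 0.00105, and adjusted p = 0.209 with an estimated correlation, and it was lost without control 1 (0.0786). With the set term it passed (camera adjusted p = 0.00576, and 0.294 with an estimated correlation).

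Genes used as markers of inhibitory and striatal neurons included some of the largest rises. In the interneuron list, Npy rose (adjusted p = 0.0151). Gad2, the GABA-synthesising enzyme and chosen after its values were seen, had 0.520 ± 0.397 and 0.501 ± 0.437 CPM (adjusted p = 0.997). Of 16 tested members 2 rose, 6 adjusted over the list alone and 8 with the set term. The list had adjusted p = 0.000381, and adjusted p = 0.241 with an estimated correlation. It was lost without control 1 (adjusted p = 0.116) and without mutant 3 (0.0725). With the set term it passed (camera adjusted p = 0.000411, and 0.294 with an estimated correlation). In the striatal list Tac1 and Ebf1, a transcription factor gene, were among the members that rose, Ebf1 from 1.88 ± 0.23 to 19.1 ± 0.63 CPM (adjusted p = 0.00302). In all 3 of 11 members rose, 3 rose and 1 fell adjusted over the list alone, 3 rose and 3 fell with the set term, and the list did not pass (adjusted p = 0.315). Its test pointed up while its median was -0.71.

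Of 8 tested oligodendrocyte lineage genes none was called over all genes, 1 rose adjusted over the list alone and 5 rose with the set term. Mbp had 26.8 ± 3.35 CPM in controls and 44.6 ± 9.45 CPM in mutants, Cnp 7.002 ± 1.65 and 13.3 ± 3.61 CPM, and Ugt8a 0.938 ± 0.174 and 3.28 ± 0.52 CPM. With 1 library left out of the fit with the set term, Mbp stayed called in 2 of 6 fits and Cnp in 1. Their adjusted p reached 0.206 and 0.152, while Ugt8a stayed called in all 6. That list had adjusted p = 0.00193, and adjusted p = 0.209 with an estimated correlation. In the astrocyte list 1 of 15 rose and 1 fell, over all genes and over the list alone, and the list did not pass (adjusted p = 0.557, upward, with a median of -0.07). The set term gave 3 that rose and 2 that fell. The member that rose in both fits was Gja1, a gap junction gene chosen after its values were seen, 63.8-fold, from 1.22 ± 0.73 to 77.3 ± 19.6 CPM (adjusted p = 0.00613). Its most abundant member, Acsl6, had 56.0 ± 8.78 and 47.8 ± 6.66 CPM. No member of the endothelial (7 tested), microglial (4), erythroid (6), choroid plexus and ependymal (7) or muscle (12) lists was called without the set term, over all genes or over the list alone, and 1 of 8 mural genes rose in both counts. Adjusted p-values of these 6 lists were 0.905, 0.356, 0.353, 0.261, 0.662 and 0.340 in the same order with mural cells last, and the erythroid list passed without mutant 1 (0.0419). In the fit with the set term 1 endothelial, 2 choroid plexus and ependymal and 2 mural genes rose and 1 microglial gene fell. No erythroid or muscle gene was called there. The most abundant members, apart from the microglial list, were Ramp2 (4.43 ± 5.92 CPM in controls and 5.22 ± 3.67 CPM in mutants), Hba-a1 (2.57 ± 2.08 and 3.30 ± 2.14 CPM), Enpp2 (4.84 ± 0.41 and 7.69 ± 1.08 CPM), Ryr1 (30.1 ± 16.04 CPM in controls, log2 fold change -1.05 ± 0.56) and Tagln (1.37 ± 0.29 and 1.24 ± 0.32 CPM). In the list for hippocampus and cortical hem 1 of 9 rose and 1 fell (2 and 1 adjusted over the list alone, 4 and 1 with the set term), and the list did not pass (adjusted p = 0.315). Its member that rose was Prox1, a factor of dentate granule neurons chosen after its values were seen, from 0.761 ± 0.154 to 15.8 ± 11.8 CPM (adjusted p = 0.0272). Zbtb20 had 28.4 ± 14.1 and 87.4 ± 89.3 CPM and was called with the set term alone (adjusted p = 0.00106).

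Of the 3 glioblastoma subtype lists, included because RP58 is studied in brain tumours, the proneural and mesenchymal ones passed upward. Bcan, a brain proteoglycan gene of the proneural list, rose from 0.473 ± 0.164 to 3.37 ± 0.69 CPM (adjusted p = 0.0386). The receptor tyrosine kinase gene Met rose 34.0-fold, from 1.04 ± 0.35 to 35.6 ± 10.3 CPM, Stat3 rose from 12.5 ± 1.48 to 33.7 ± 5.17 CPM, and Fosl2 fell from 53.8 ± 0.61 to 25.2 ± 4.55 CPM (adjusted p = 0.00435, 0.0250 and 0.0490). In the proneural list 3 of 18 rose, 4 adjusted over the list alone, with adjusted p = 0.0304, and adjusted p = 0.263 with an estimated correlation. It did not pass with the set term (adjusted p = 0.190), without control 1 (0.117) or without mutant 3 (0.0565). In the mesenchymal list 2 of 22 rose and 1 fell, 2 and 2 adjusted over the list alone, with adjusted p = 0.0487, and adjusted p = 0.510 with an estimated correlation. It was lost without control 1 (0.333) and without mutant 3 (0.235). With the set term it passed (camera adjusted p = 0.00576, and 0.294 with an estimated correlation). In the classical list 2 of 20 rose, 2 rose and 2 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.341). Akt2, its most abundant member, had 163 ± 34.4 CPM in controls and 147 ± 30.5 CPM in mutants.

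**Figure D4:**
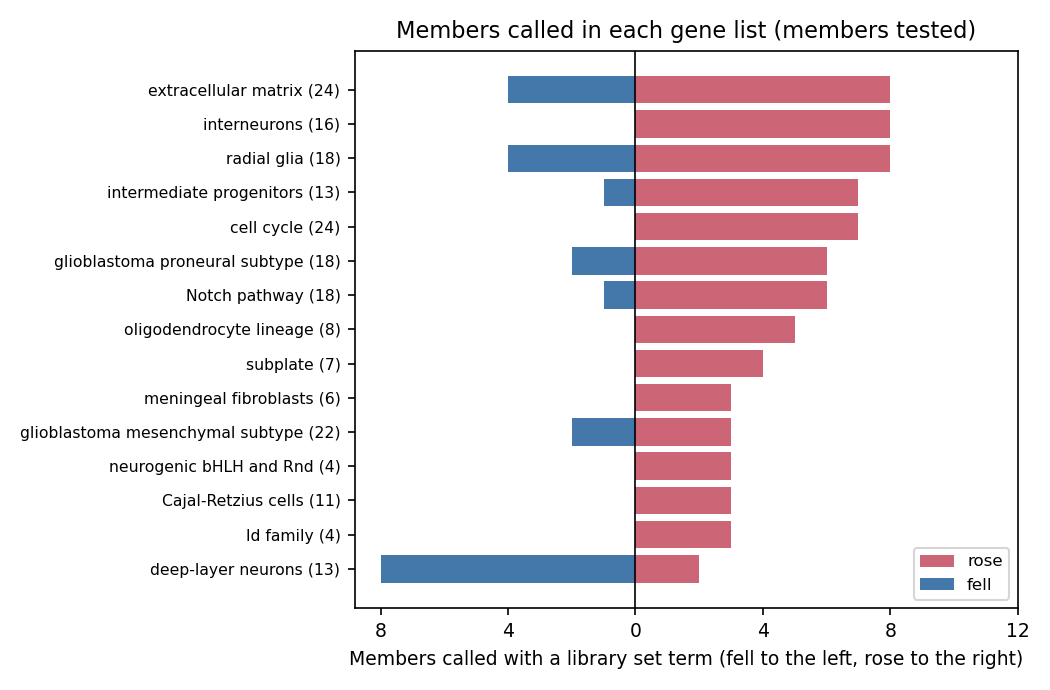
Number of members called with the set term in each of the 15 gene lists past adjusted p 0.05 without it, with members that rose to the right and members that fell to the left, and the number tested in parentheses. In the deep-layer list 8 of 13 members fell and 2 rose, and in the interneuron list 8 of 16 rose and none fell.

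Stress and metabolism lists did not pass without the set term. In the list of p53 response and apoptosis 1 of 17 rose and 1 fell, over all genes and over the list alone (adjusted p = 0.315), 5 rose and 3 fell with the set term, and Trp53inp1 had 180 ± 26.1 and 196 ± 33.4 CPM. No immediate early or dissociation gene of 15 was called in either count (list adjusted p = 0.315), and Hsp90aa1 had 875 ± 146 and 813 ± 184 CPM. The set term gave 2 of that list that rose and 1 that fell. In the list of hypoxia and glycolysis 1 of 18 fell in both counts (list adjusted p = 0.745). With the set term 6 fell and 1 rose and that list passed downward (adjusted p = 0.00576, and adjusted p = 0.325 with an estimated correlation). Gapdh, its most abundant member, had a log2 fold change of -0.54 ± 0.10 with the term (adjusted p = 0.0125), a call lost without control 1, control 2, control 3 or mutant 3 (adjusted p up to 0.104). No mitochondrially encoded gene of 15 and no sex-linked gene of 5 was called in either count or fit (list adjusted p = 0.724 and 0.421). The mitochondrial RNA mt-Rnr2 lay between 464 and 946 CPM in the fixed-length set and between 142400 and 160300 CPM in the estimated-length set. Xist, the RNA that silences an X chromosome in females, had 0, 484 and 1.52 CPM in controls 1, 2 and 3 and 0.116, 150 and 577 CPM in mutants 1, 2 and 3. Controls 2 and 3 share genotype and technical set yet differed in Xist, as did mutants 1 and 2. By this marker the libraries of a genotype differ in the sex of their embryos, and sex is not spread evenly over the genotypes. Sex was not a term in any fit.

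Single transcripts gave few calls without the set term. Of 48353 transcripts tested, 5 passed, 4 upward and 1 downward, and none did whichever library was left out. With the set term 677 passed, of which 440 rose and 237 fell, and 61 of them belonged to no gene of the annotation used. No gene had transcripts called in opposite directions with the set term. In total 15 of the 37 lists passed with the preset correlation, and none did with an estimated one. Of the same lists 9 passed fry's directional test and 26 its mixed test. Some lists share members, so those that passed are not separate results. Hes1 is in the Notch and radial glia lists, Neurog2 in the neurogenic and intermediate progenitor lists, and Pdgfra in the meningeal and oligodendrocyte lists. The loss with an estimated correlation does not show that correlated genes explain these lists. The Notch, Id, meningeal, oligodendrocyte and proneural lists were lost although their estimated correlations (-0.026, -0.154, -0.183, -0.04 and -0.024) lay under the preset 0.01.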

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

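The fits within each technical set, the set term for single transcripts, the estimated correlation with the set term and the leave-one-out and scaling fits with the set term were chosen after the result was seen. The cause of each change named here was not tested unless stated. No paired analysis was possible because the numbers in the titles differ between the genotypes and the replicate numbers used here only follow deposition order.

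The number of genes changed in mutant against control, 400 (67.5% rose), became 1026 with DESeq2, 2537 with the set term, 2680 with 1 surrogate variable, 1606 within the fixed-length set and 1345 within the estimated-length set, and lay between 84 and 329 with 1 library left out. The 400 genes were all among the calls of DESeq2, the set term and the surrogate variable. Limma on log2 TPM called 0 genes with a pseudocount of 1, with 0.1 and with no filter (249, 252 and 919 at an unadjusted p under 0.05). The share that rose was 53.1% with the set term and 53.5% with 1 surrogate variable, and 67.9% to 81.3% with 1 library left out. With other scalings, filters, limma-voom, the effective-length offset or protein-coding genes only, 292 to 485 genes were called, and 271 in a test against a fold change of 1.5. In that fit with the set term, the count lay between 1294 and 3034 with 1 library left out and between 2504 and 2772 with other scalings. The median log2 fold change of all genes was -0.055, and it moved past 0.1 in size with upper-quartile factors (-0.105), DESeq2 (-0.145) and filtered TPM (0.66 and 0.76). Transcripts went from 5 to 677 with the set term and to 0 with any library left out.

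Zbtb18 was lower in each setting. Its log2 fold change, not called at -3.04, passed with DESeq2 (-3.06), the set term (-3.48), 1 surrogate variable (-3.62), within the fixed-length set (-5.36) and within the estimated-length set (-1.61), and lay between -5.22 and -2.56 with 1 library left out. Of the other 81 named genes, the set term called 21 more and ended no call, DESeq2 called 8 more, and the effective-length offset ended 12 calls, limma-voom 7, no filter 7 and upper-quartile factors 6. Leaving out control 1, 2 or 3 ended 13, 29 or 28 calls, and leaving out mutant 1, 2 or 3 ended 31, 30 or 13. With the set term 4 of them changed sign, of which Tubb3 (-0.24), Ramp2 (-0.37) and Hba-a1 (-0.08) were called in neither fit, and 1 that is not reported here was called with the term.

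Of the 37 lists 15 passed. None (0) did with an estimated correlation, with or without the set term, while fry called 9 for direction and 26 for any change, and 9 to 16 passed with 1 library left out. The adjusted p of lists that crossed 0.05 follows. With the set term, proneural glioblastoma was 0.19, glutamatergic and synaptic genes 0.013 (down) and hypoxia and glycolysis 0.00576 (down). With 1 surrogate variable, deep-layer neurons were 0.0631 and proneural 0.174. Within the fixed-length set, radial glia were 0.106, deep-layer neurons 0.0604, proneural 0.0848, mural cells 0.0279 and hypoxia 0.0342. Within the estimated-length set, radial glia were 0.0784, proneural 0.514, glutamatergic genes 0.00668 and hypoxia 0.00572. With DESeq2, upper-layer neurons were 0.0118 (down), striatal neurons 7.4e-05 and classical glioblastoma 0.045. With limma-voom, extracellular matrix was 0.0558, mesenchymal glioblastoma 0.144 and proneural 0.0503. With no filter, the oligodendrocyte lineage was 0.0845 and proneural 0.0607. With at least 1 CPM in 3 libraries, the Id family was 0.175, matrix 0.38, mesenchymal 0.343 and proneural 0.0651. With protein-coding genes only, matrix was 0.0597, mesenchymal 0.109 and proneural 0.0597. Mesenchymal was 0.0687 with library size only and 0.131 with the effective-length offset. On log2(TPM + 1), the Id family was 0.221, radial glia 0.431, the oligodendrocyte lineage 0.621, matrix 0.409, mesenchymal 0.436, proneural 0.5 and sex-linked genes 0.0424. With a pseudocount of 0.1 these were 0.232, 0.167, 0.583, 0.403, 0.344, 0.514 and 0.0141. With TPM and no filter, neurogenic genes were 0.114, deep-layer neurons 0.189, hippocampus and hem 0.000241, the oligodendrocyte lineage 0.13, meningeal fibroblasts 0.191, classical 0.00151 and proneural 0.114.

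With 1 library left out, the adjusted p ranged from 0.000108 to 0.116 for Cajal-Retzius cells, 7.66e-06 to 0.116 for interneurons, 0.000646 to 0.0786 for meningeal fibroblasts, 0.00148 to 0.337 for matrix, 0.0158 to 0.333 for mesenchymal, 0.0142 to 0.117 for proneural and 0.0419 to 0.584 for erythroid genes. In simulated counts at these depths, 12% of 4-fold changes were recovered without and 76% with the set term, so the spread between the sets limited the calls without it.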

Other observations

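Of the tests in this part, the effective-length division, the splits of the libraries and the test of opposite directions within gene families were chosen before the result was seen, and the others after it.

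Some genes outside the naming rule, chosen after their values were seen, also changed. Bcl2, which protects cells from death, fell from 60.4 to 13.6 CPM (log2 fold change -2.15, adjusted p = 0.0168, edgeR), and its antagonist Bcl2l11 rose from 8.62 to 40.2 CPM (2.22, adjusted p = 0.00435). Gene families were defined as genes whose symbols share a stem before the final number, so some join unrelated genes. In a scan of 439 such families in 2 directions (878 tests), 0 passed adjusted p 0.05 and the lowest adjusted p was 0.213. The smallest p was that of the calmodulin kinase genes, of which 5 of 10 fell with the set term (one-sided Fisher's exact p = 0.000579).

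The libraries separated by technical set before genotype. Replication-dependent histone transcripts, which lack a poly(A) tail, were higher in the estimated-length set for 57 of 58 genes, with a median log2 difference of 8.7 against 0.11 over all genes. Dividing counts by effective length left 80.2% of the variance on the first component. The estimated counts had not been scaled by effective length, so the division could not undo an effect of the fragment-length setting on them. It does not decide whether that setting was a cause. A candidate explanation is that RNA was selected differently for the sets, for example by poly(A) tail in the fixed-length set, although the labels name 1 kit.

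Zbtb18 kept 32.8% of the control level in mutant 3 and 2.5% and 2.4% in mutants 1 and 2. The 36 genes described above, which were called, fell at least 8-fold in the fixed-length set and had at least 2 CPM in controls, were compared with it. They kept a median of 8.8% of the control level in mutant 3 (quartiles 5.2% and 17.6%), and 4 of them kept at least the share of Zbtb18. The median argues against control RNA mixed into mutant 3 as the whole cause. The single-exon transcript model held 61.7% of the gene's counts in mutant 3, and its level was above the controls there but below the control in mutants 1 and 2. Transcribed sequence left by the deletion and seen in 1 library type may account for part of this, and it cannot be told apart from a property of this library, because the estimated-length set holds 1 mutant.

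Some members of the radial glia and Notch lists rose. The 9 transcripts abundant in radial glia (Fabp7, Vim, Slc1a3, Dbi, Sparc, Hes5, Ttyh1, Mfge8 and Nes) had a median log2 fold change of -0.13 with the set term, with 2 that rose and 4 that fell, while the radial glia list fixed beforehand had a median of 0.90, with 8 that rose and 4 that fell. Members went both ways, so radial glia carried into the mutant libraries stay open. Dividing intermediate progenitors carried in could raise cell cycle genes too, whose median was 0.56. The cell cycle list does not bear on a larger share of newborn neurons, which no longer divide. None of these sources can be told apart from a change within the neurons, because no value here separates cells. A failure of the mutant neurons to silence progenitor genes is the biological hypothesis that the design offers, and it was not tested.

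With 3 libraries against 3, the 10 splits are too few for a share under 0.05. For genes the real split gave 400 and the highest other 10068, and for transcripts 5 and 28053. That other split, in 2 of 10 as large with the real one, follows the technical sets and points to that structure of the libraries. With the set term and the make-up of the sets kept, the real split gave 2537 genes and the highest of the other splits 0 (1 of 9 as large). For lists the real split gave 15 and the highest other 6 (1 of 10).

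The hypothesis that members of a gene family replaced each other predicted more opposite directions within families than by chance. Of 2369 pairs of called genes of 1 family, 46.5% had opposite directions, against a median of 49.8% over 10000 shuffles (one-sided permutation p = 0.986). The prediction was not met for families defined by the stem of the symbol. Since some of these join unrelated genes, true relatives alone were not tested.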
